A study of Drosophila melanogaster with 3 samples.

How the data were processed

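ChIP-seq peak lists from 3 biological replicates of whole Drosophila melanogaster embryos, aged 0 to 24 h and carrying a cbt-eGFP fusion, were analysed. Per the labels, chromatin was sonicated to 200 to 800 bp and precipitated with an anti-GFP antibody, and the genome build is dm6. The peak caller, the aligner, their versions and the control used are not given in the sources used here, and control samples were not analysed here. Reads and coverage were not used here, so the sequencing depth of each sample is unknown and the number of peaks is the only measure of yield.

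The authors made each list by an analysis of the irreproducible discovery rate (IDR), which ranks peaks by how well they repeat between data sets, per the file headers. There were 7 lists: 1 for each replicate, made from that sample's alignment, and 4 made from the alignments of all 3 samples. The authors called 1 of these 4 conservative. Which replicates entered each of the 4 lists is not given in the sources used here. Each list was deposited as a ranked version with 20 columns and no threshold and as a thresholded version with 10 columns. The deposited signal of a peak is the peak caller's own value per peak, and whether it was scaled to depth or to a control is not stated. The deposited score of a peak is the log2 of the global IDR times -125, at most 1000, which was checked on the values and held for all ranked peaks within a tolerance of 1. The ranked lists also give the deposited −log10 of the global IDR, which is capped at 5. Every thresholded list stopped at a global IDR of 0.01. Some peaks past that limit were missing from the thresholded lists, and these are called left out. The columns that describe the separate data sets compared within each series-wide ranked list, 8 in each of 4 lists and 32 in all, could not be mapped to samples and were not used.

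Peaks were placed on the 6 main arms, and gene positions came from the Ensembl annotation of BDGP6.54. Positions are 1-based. A promoter summit was within 500 bp of any annotated transcription start of a protein-coding gene, and other summits were classed as coding exon, untranslated exon, intron or intergenic in that order. A gene was called bound when a conservative summit lay within 500 bp of any of its starts. For the named sites, each conservative peak was matched to the overlapping ranked peak of each replicate with the nearest summit. The replicate's signal was divided by its median over the 3039 conservative peaks (92.5%) matched in all 3 replicates, and the mean and SD over the 3 replicates are given. For cbt the divisor was the median of the replicate's thresholded peaks.

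The comparisons, tests, gene lists, motifs and the rule for named genes were chosen before the data were examined. The rule named cbt itself, the genes with a coding start within 500 bp of the 15 conservative peaks of highest signal that overlap a thresholded peak in all 3 replicates, the 5 highest conservative peaks with summits over 1000 bp from any coding start, and up to 4 bound members of highest signal per gene list. Sites among the 15 with no start in reach are given with the gene they lie in or the nearest one, and this addition, like the further members Mondo, bigmax and sug, was chosen after the values were seen. Replicate overlap was a shared base of at least 1 bp, tested one-sided against 1000 random placements of the other list on the same arms. Promoter share was tested two-sided against 1000 random placements of the summits. The 23 gene lists were compared with all other coding genes on the arms by Fisher's exact test. One symbol each of the autophagy, Notch, germline and testis lists was not matched in the annotation.

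Sequence was read in windows of 101 bp around the summit and in windows of the same width centred 450 bp away on a side drawn at random, which were compared by an exact binomial test of discordant peaks for 17 motifs and 2080 6-mers, collapsed with their reverse complements. The GC-matched background was an equal number of ranked peaks with a global IDR over 0.05, matched on location class and on GC content in bins of 2 percentage points, which found a partner for 3281 peaks (99.8%). Signal was compared between peaks with and without a motif by a permutation test with 100000 resamples. Regions present in 3 replicates were compared with those present in 1 by Fisher's exact test, and the X share by an exact binomial test. Adjusted p values are Benjamini-Hochberg values, called under 0.05. Intervals are 95% Wilson intervals, and a count of 0 allows up to 3 counts of the total.

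Alternatives were the other series-wide lists, other IDR limits, the left-out peaks added back, other windows and overlap rules, other gene assignments and backgrounds, an equal number of peaks per replicate, and each replicate left out in turn. Stricter and looser IDR limits, the added-back peaks, equal peak numbers, peaks present in all 3 replicates, ranked peaks as the promoter background, a second matched draw, and the leaving out of replicates for overlap and correlation were chosen after seeing the data. For the conservative list, leaving out a replicate meant using the peaks shared by the other replicates' thresholded lists. With 3 replicates, no test for outlying samples was made.

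The code was tested on simulated data. Flank windows of the summits were compared with the flank windows on the other side. A 6-mer planted in 5% or in 2% of the latter ranked first among 2080, and with none planted 0 were called. No summit windows were used, so this does not check calls that arise from the difference in GC content between summits and flanks. Random sets of bound genes gave a called list in 3 of 100 draws, and a ribosomal list with added members was found in 100 of 100. Random summits were called at promoters in 0 of 20 draws, and a list sharing 40% of its peaks with another was found to share 41.6%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.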

Results

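Binding of the zinc finger protein cabut, encoded by cbt and a member of the KLF (Krüppel-like factor) family of transcription factors, was mapped by ChIP-seq in whole Drosophila melanogaster embryos aged 0 to 24 h. The embryos carried cbt fused to eGFP, and chromatin was precipitated with an antibody to GFP. The series held 1 group of 3 biological replicates, and no control samples were analysed here. Each replicate had a thresholded peak list, with 2382, 1551 and 2425 peaks in replicates 1, 2 and 3. The authors also gave 4 lists made from all 3 samples, of which the one they called conservative held 3291 peaks and the others 2736, 2944 and 4724. The conservative list was used wherever a single set of sites was needed, and 3287 of its summits lay on the 6 main chromosome arms (2L, 2R, 3L, 3R, 4 and X) of dm6. Sequencing depth is unknown, because only peak lists were analysed. The signal of a peak is the authors' own value, and all intervals are 95% Wilson intervals that cover counting error only.

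The design has 1 group, so the comparison it implies is of the replicates with each other. Peaks at the lipase gene bmm, the glycerol kinase gene Gk2 and the gluconeogenic gene Pepck1 were among 1147 conservative peaks (34.9%) that overlapped a thresholded peak in all 3 replicates. At least 1 replicate's thresholded list held 2587 of the conservative peaks (78.7%). Replicate 2 had the fewest peaks and the largest shared share, with 80.8% (78.7 to 82.7%) of its 1521 peaks on the arms found in replicate 1 and 87.2% (85.5 to 88.8%) in replicate 3. Of the 2381 peaks of replicate 1, 51.9% (49.9 to 54.0%) overlapped a peak of replicate 2 and 66.1% one of replicate 3. Of the 2394 peaks of replicate 3, 65.3% were in replicate 1 and 55.5% in replicate 2. The highest share in 1000 random placements was 2.10%, and each of the 6 ordered pairs had a one-sided permutation p of 0.001, the smallest that 1000 placements can give. Across shared peaks, the signal in one replicate correlated with that in another, with Spearman's rho of 0.776 between replicates 1 and 2 (1237 peaks), 0.746 between 1 and 3 (1574 peaks) and 0.806 between 2 and 3 (1327 peaks). Pearson's r of the log2 signal was 0.789, 0.771 and 0.816 for the same pairs. These are correlations across peaks, which are not independent replicates, and over all ranked peaks the mean rho was 0.344.

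**Figure D1:**
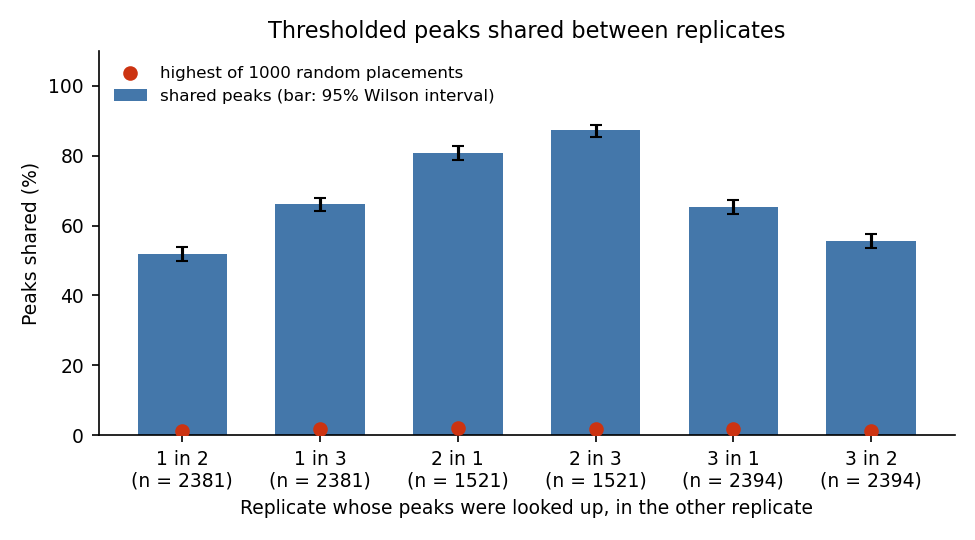
Share of each replicate's thresholded peaks (y axis, %) that overlap a peak of another replicate (x axis, with n the peaks looked up); bars show the share with its 95% Wilson interval and red points the highest of 1000 random placements. Shares ran from 51.9% for replicate 1 in replicate 2 to 87.2% for replicate 2 in replicate 3, against at most 2.10% by placement.

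Sites found in every replicate were more often at promoters than sites found in a single replicate. The 3 thresholded lists merged into 3217 regions, of which 1126 were present in 3 replicates, 669 in 2 and 1422 in 1. A coding start lay within 500 bp of 545 (48.4%) of the regions present in 3 and of 612 (43.0%) of those present in 1, a difference of 5.36 percentage points (two-sided Fisher's exact p = 0.00728). The call ended with a window of 200 bp around the start (0.755 points, exact p = 0.701), and it ended when replicate 2 (2.79 points, exact p = 0.122) or replicate 3 (3.06 points, exact p = 0.124) was left out. The KLF and Sp box CCRCCC was in 6.48% of regions present in 3 replicates and 7.88% of those present in 1 (exact p = 0.192). Without replicate 1 that difference was -2.02 points (exact p = 0.0433).

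The conservative list held no summit within 500 bp of the single annotated start of cbt itself (FBgn0043364, 2L 476446 to 479688, minus strand). The cbt gene lies inside ush, a gene for a GATA cofactor, and the highest peaks near it were absent from the thresholded lists although they passed the same limit in the ranked lists. Within 10 kb of cbt, the ranked list behind the conservative list held 39 peaks, of which 15 passed a global IDR of 0.01, 6 were kept and 9 were left out. The highest was left out, with a signal of 2659 and rank 4, at 2L 480556 to 481704 in a ush intron (summit 480880, position -1192 bp from the cbt start). A further left-out peak in the untranslated part of cbt had a signal of 1688 (2L 478730 to 479258). The peak at the cbt start, at position -134 bp, had a signal of 149.5 and was also left out. The kept peaks included 2 in the ush intron, with signals of 1336 (2L 484575 to 485102) and 1611 (2L 485630 to 486066). In the replicates, the highest ranked peak of this region was 12.8 ± 2.83 (SD, n = 3) times the median signal of the replicate's thresholded peaks. The highest ranked peak within 500 bp of the start of cbt was 1.52 ± 1.30 (SD, n = 3) times that median, a mean that replicate 1 raised with 3.02 against 0.711 and 0.842. Replicate 3 had 2 peaks there, the higher at position -321 bp, and the one closer to the start was at 0.410. That closer peak and the replicate 2 peak did not pass a global IDR of 0.01. Of the passing peaks of the region, 8 of 15, 6 of 9 and 9 of 16 were left out in replicates 1, 2 and 3.

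**Figure D2:**
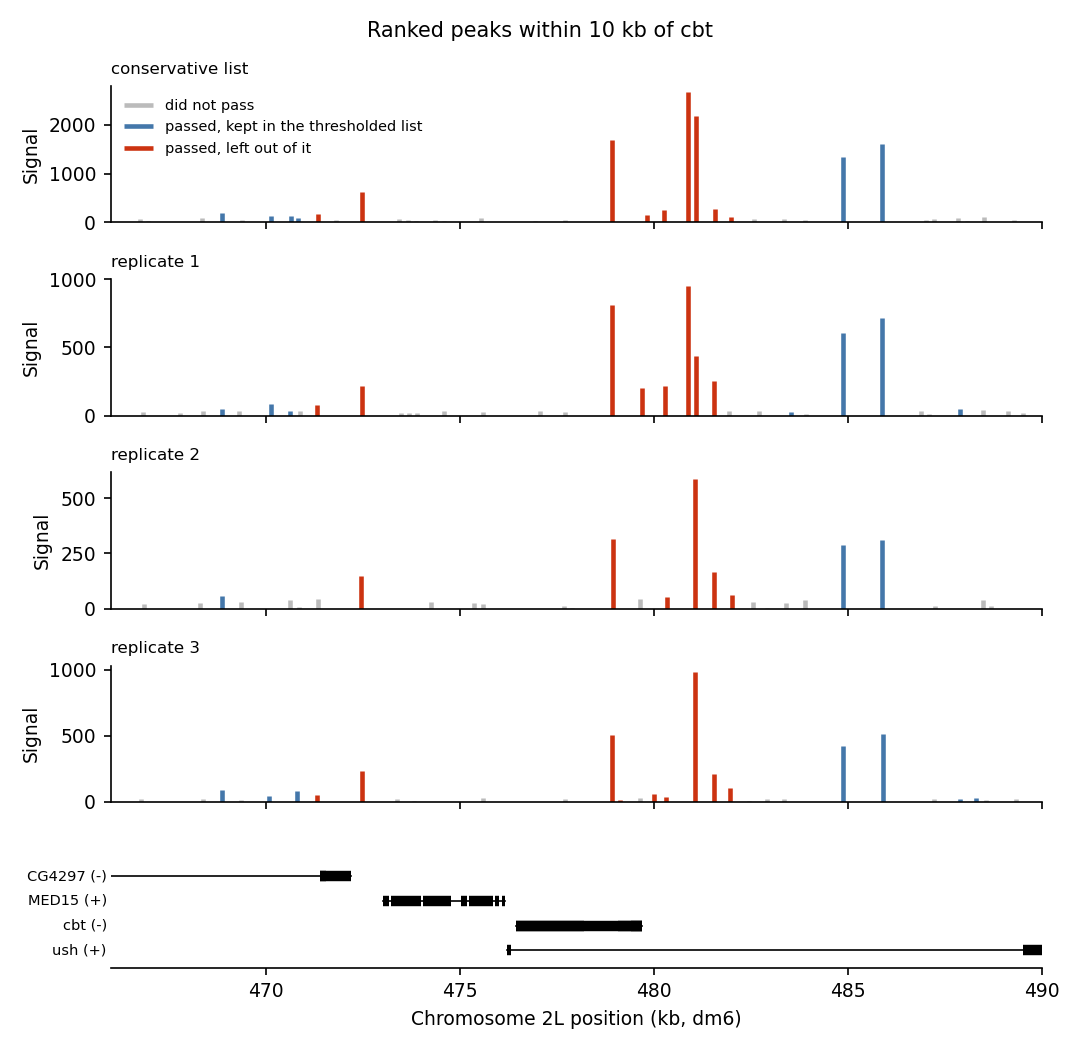
Ranked peaks within 10 kb of cbt on chromosome 2L (x axis, kb, dm6), with the signal of each (y axis, the authors' value) in the conservative list and in the 3 replicates; gene models are drawn at the bottom with exons as boxes. Red bars mark passing peaks missing from the thresholded list, with the highest at a signal of 2659 in the conservative list and 953.4, 587.4 and 982.6 in replicates 1, 2 and 3.

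The highest peaks of the map lay in the lipase gene bmm, near Tektin-C and in the overlapping genes kermit and Lpin, with signal 20.3 to 30.9 times the median. The 15 conservative peaks of highest signal that were shared by all 3 replicates were also the 15 highest of the list, and only 4 of them had a summit within 500 bp of a coding start. The top peak was in an intron of bmm (FBgn0036449), the gene of the triglyceride lipase brummer. It lay at 3L 14780916 to 14781482, 5094 bp from the nearest coding start, that of mop, with a signal of 4786. Its signal was 30.9 ± 2.98 (SD, n = 3) times the median of the conservative peaks matched in all 3 replicates. A second peak in bmm (3L 14785175 to 14785592) reached 13.8 ± 2.92 times the median. The next highest site was intergenic and nearest the tektin gene Tektin-C (FBgn0035638, 3L 5797251 to 5797622), at 22.9 ± 3.14 times the median. It was followed by one in introns of kermit and of the phosphatidate phosphatase gene Lpin (2R 8149857 to 8150276), at 20.3 ± 2.89. The 4 promoter peaks lay at Gk2, which encodes a glycerol kinase (FBgn0035266, 3L 1738359 to 1738797, 15.5 ± 2.14), at cv-2, which encodes a BMP-binding protein (FBgn0000395, 2R 21379405 to 21379755, 14.2 ± 2.67), at CG45087, and at CG33474 (2R 10421368 to 10421740, 14.0 ± 0.712). The start of CG45087 is shared by Pepck1 (FBgn0003067), which encodes phosphoenolpyruvate carboxykinase, and that peak (2R 18536383 to 18536833) reached 14.0 ± 1.17.

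Further high peaks lay away from starts. The 5 highest with summits over 1000 bp from any coding start were both bmm peaks, one in an intron of Roc2 (2R 11657795 to 11658202, 15.1 ± 3.01), one 2082 bp from the start of the acyltransferase gene LPCAT (X 9581851 to 9582257, 14.7 ± 1.502) and one in an intron of nebu (3L 12834445 to 12834821, 14.0 ± 2.88). The remaining sites among the 15 were nearest CG18135 (14.8 ± 3.37), the clathrin adaptor gene Gga (14.5 ± 1.81), the peroxiredoxin gene Prx6c (14.2 ± 0.275) and CG11050 (12.2 ± 1.01). All values are multiples of the median signal, with the SD over 3 replicates.

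Where cabut was bound relative to genes was asked next. Promoters were the class most enriched in summits, and coding exons were nearly free of them. Of the 3287 summits, 1385 (42.1%, 40.5 to 43.8%) lay within 500 bp of a coding start, 1315 (40.01%) in introns, 490 (14.9%) between genes, 63 (1.92%) in untranslated exons and 34 (1.03%) in coding exons. Ranked peaks that did not pass lay at promoters in 12.2% and in coding exons in 20.4% of 118072 cases. At promoters, 1069 summits (77.2%, 74.9 to 79.3%) were upstream of the nearest start, and the median position was -108 bp. Promoters held 52.7% of the tenth of summits with the highest signal and 38.7% of the tenth with the lowest. The latter share is uncertain, because those summits include 98 peaks with a pooled signal under 20. The replicate peaks that overlapped them had an ordinary signal (median 0.742 times that of the matched peaks). A match needed only an overlap, so that value can belong to a neighbouring summit. Random placement of the summits put 11.4% at promoters on average and 13.2% at most, a 3.68-fold excess for the real summits (two-sided permutation p = 0.002, the smallest that 1000 placements can give).

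**Figure D3:**
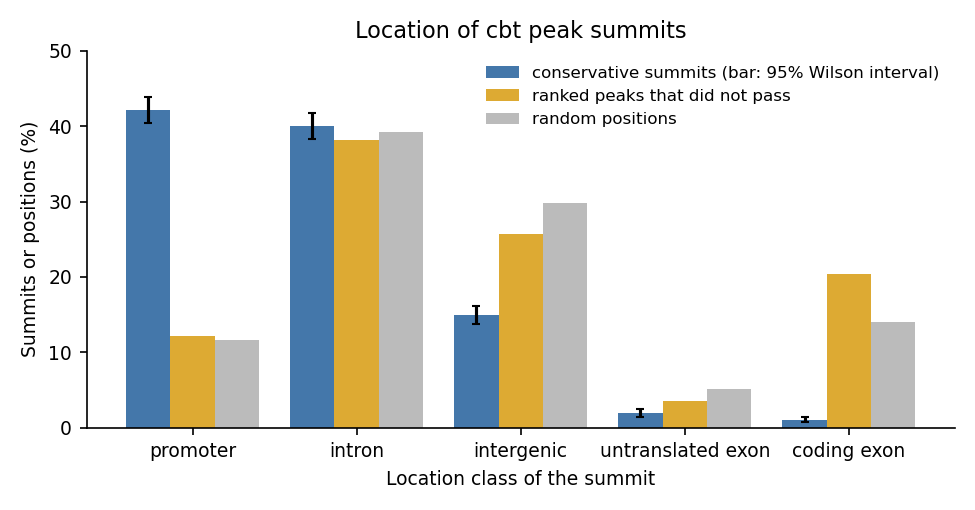
Share of positions (y axis, %) in each location class (x axis) for the 3287 conservative summits with 95% Wilson intervals, for ranked peaks that did not pass and for random positions. Promoters held 42.1% of summits against 12.2% of peaks that did not pass and 11.7% of random positions, and coding exons 1.03% against 20.4% and 14.1%.

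A summit lay within 500 bp of a start of 1686 of 13945 protein-coding genes (12.1%), and those genes are called bound here. Of these, 436 were bound only through a summit nearer to another gene. Without replicate 1, 2 or 3, where the peaks shared by the other replicates replaced the conservative list, the count was 827, 959 or 765.

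Among the 23 gene lists, those of cytoplasmic ribosomal proteins, sugar metabolism and the stress response were bound more often than other genes. Of 86 genes for cytoplasmic ribosomal proteins, 49 were bound (57.0%, 46.4 to 66.9%), against 11.8% of other genes. Among them the peaks at RpS27 (2.69 ± 0.377 times the median signal, SD, n = 3), RpL32 (2.69 ± 0.518), RpL7 (2.23 ± 0.576) and RpL23A (2.14 ± 0.409) were highest. Of 29 genes of sugar sensing and metabolism, 17 were bound (58.6%, 40.7 to 74.5%). They included Pepck1, the glycolytic genes Gapdh2 (5.94 ± 0.895), Ald1 (4.36 ± 1.17) and Eno (2.07 ± 0.266), and the genes for the sugar sensors Mondo and bigmax and for their target sug. Of 19 heat shock and stress genes, 11 were bound (57.9%, 36.3 to 76.9%), with the highest peaks at the stress transcription factor genes Xrp1 (3.45 ± 0.102) and Atf3 (3.28 ± 1.13) and the chaperone genes Hsp27 (3.27 ± 0.556) and Hsp83 (1.68 ± 0.704). None of 119 olfactory and gustatory receptor genes was bound, a count of 0 that allows a share of up to 2.52%.

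These 4 lists passed a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 23 lists. The odds ratio and adjusted p were 9.89 and 4.19e-22 for ribosomal proteins, 10.4 and 3.32e-08 for sugar genes and 10.1 and 1.34e-05 for stress genes, and the adjusted p was 2.32e-06 for the receptors. The test was made on the conservative list, which pools samples, so it does not measure the spread between replicates. The background was all other coding genes whatever their expression, which was not measured, and no control precipitate was analysed. None of the 4 calls is therefore shown to be particular to cabut. The called lists also passed with only the peaks present in all 3 replicates and with each replicate left out, but their distance from other genes in percentage points was smaller there. Fewer genes of any kind were bound in these settings, so a smaller distance in points need not mean a weaker enrichment. For ribosomal proteins it was 45.2 points in the conservative list, 12.3 with the peaks present in all 3 replicates and 13.9, 31.7 and 12.03 without replicate 1, 2 and 3. For sugar genes it was 46.6 points, then 22.4 and 25.2, 27.7 and 25.6, and for stress genes 45.9, then 26.4 and 25.7, 30.01 and 36.7. For the receptors it was -12.2 points, then -5.26 and -5.98, -6.94 and -5.53. The highest adjusted exact p over all alternatives was 0.000778, 0.000974, 0.00456 and 0.0171 for these lists.

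**Figure D4:**
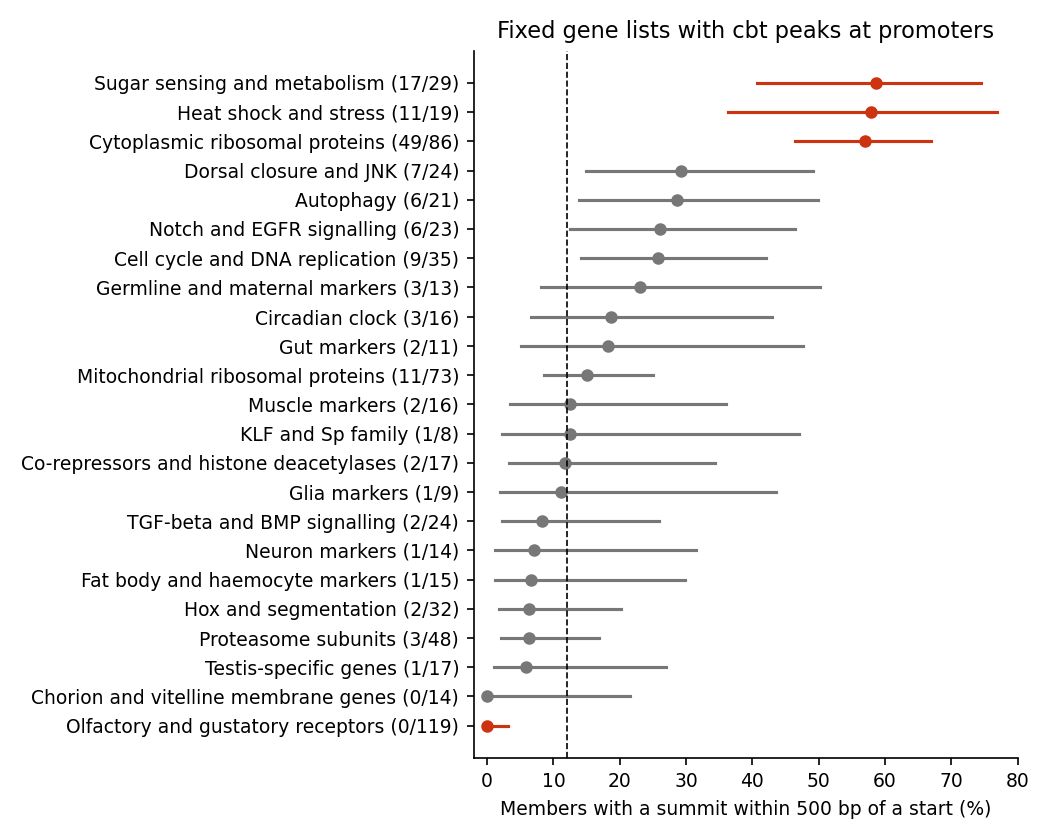
Share of each fixed gene list's members with a conservative summit within 500 bp of a start (x axis, %), as points with 95% Wilson intervals and bound/total counts beside each list name (y axis); the dashed line is the share over all coding genes and red marks adjusted p under 0.05. The 3 lists above the line and past the test lay between 57.0% and 58.6%, against 12.1% of all genes, and the receptors lay at 0%.

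The other 19 lists did not pass the test. Of 24 genes of dorsal closure and JNK signalling, the pathway that drives epidermal closure in the embryo, 7 were bound (29.2%, adjusted exact p = 0.0925), with the highest signal in the conservative list at ush, sqh, raw and pnr. The cell cycle list had 9 of 35 bound (adjusted exact p = 0.111), with Dp, RnrS, Cdk1 and CycE highest, and the autophagy list 6 of 21 (0.111), with Atg2, Atg17, Atg18a and Atg9. The Notch and EGFR list had 6 of 23 (0.147), with spi, aop, aos and pnt, and the germline list 3 of 13 (0.515), namely orb, bcd and gcl. For mitochondrial ribosomal proteins, 11 of 73 genes were bound (15.1%, adjusted exact p = 0.770), with the highest peaks at mRpL41 (10.9 ± 1.51 times the median, SD, n = 3), mRpS23 (8.84 ± 1.22), mRpS10 (8.29 ± 1.10) and mRpL23 (7.27 ± 1.30). Many of these peaks were nearer the start of another gene: mRpS7 for Cdk1, CG12093 for Atg2, Xe7 for Atg17, Cdc16 for orb, CG14767 for gcl, CenG1A for mRpS23 and Art3 for mRpS10. Only 6 of the 9 cell cycle genes, 3 of the 6 autophagy genes, 1 of the 3 germline genes and 5 of the 11 mitochondrial ribosomal genes had a summit nearest to their own start.

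For the circadian list 3 of 16 genes were bound (sgg, Pdp1 and dco, adjusted exact p = 0.763), and for the proteasome 3 of 48 (Rpn3, Prosalpha3 and Rpn6, 0.622). Hox and segmentation genes had 2 of 32 bound (bcd and en, 0.763), gut markers 2 of 11 (fkh and GATAe, 0.971), and TGF-beta and BMP genes 2 of 24 (wit and shn, 1.00). Muscle markers had 2 of 16 (tin and sls, 1.00) and co-repressors and deacetylases 2 of 17, the co-repressor genes gro (3.17 ± 0.496 times the median, SD, n = 3) and sbb (2.41 ± 0.143), at an adjusted exact p of 1.00. A single gene was bound among 9 glia markers (moody), 14 neuron markers (elav), 15 fat body and haemocyte markers (ush), 17 testis genes (bgcn) and 8 KLF and Sp genes (dar1), each at an adjusted exact p of 1.00. None of 14 chorion and vitelline membrane genes was bound (adjusted exact p = 0.763), which allows up to 21.4%. Assigning each summit to the nearest start within 5 kb added calls for dorsal closure (31.9 points over other genes, adjusted exact p = 0.000776), Notch and EGFR (20.8 points, 0.0331) and TGF-beta (23.5 points, 0.0139). That test took no account of the spacing of genes or their number of starts, which can change how many summits a gene receives. Notch and EGFR genes were also called in the list of 2736 peaks (24.5 points, adjusted exact p = 0.00678), in that of 4724 (23.6 points, 0.0248) and at an IDR under 0.05 (22.5 points, 0.0327), where dorsal closure was called as well (25.1 points, 0.0152). Autophagy was called at an IDR under 0.001 (21.1 points, adjusted exact p = 0.0167). Over all alternatives the adjusted p ran up to 1.00 for each of these 4 lists, from 0.000776 for dorsal closure, 0.00678 for Notch and EGFR, 0.0139 for TGF-beta and 0.0167 for autophagy.

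Sequence at the summits was examined to see which motifs mark the sites. Runs of C were more frequent at summits: GCCCCC was in 250 of 3281 summit windows (7.62%) against 101 (3.08%) of GC-matched peaks that did not pass. The same held for AGGGGG (220 against 99) and AGCCCC (186 against 85), read on either strand. The long KLF box RCCMCRCCC was in 72 of 3287 summits against 33 flanks (log2 ratio 1.11, adjusted exact p = 0.00303), and the GATA site WGATAAG in 160 against 112 (0.54, adjusted p = 0.0142). Both stayed called against GC-matched peaks (log2 ratio 0.95 and 0.68, adjusted exact p = 0.00797 and 0.00303). The short KLF and Sp box CCRCCC did not differ between 239 summits and 235 flanks (log2 ratio 0.03, exact p = 0.885), except that without replicate 1 it was lower at summits (log2 ratio -0.65, adjusted exact p = 0.0187, in a range over alternatives from 0.0187 to 1.00).

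The DRE (34 against 10, log2 ratio 1.72, adjusted exact p = 0.00330) and the TATA box (67 against 40, 0.75, adjusted p = 0.0368) were higher and the Mad site lower (25 against 56, -1.18, adjusted p = 0.00362) at summits than in flanks. None of these 3 stayed called against GC-matched peaks (adjusted exact p = 0.203, 0.827 and 0.610). Without replicate 1, 2 or 3 the DRE was not called (log2 ratio 0.79, 0.87 and 0.49, adjusted exact p = 0.601, 0.397 and 0.730). Without replicate 3 the Mad site (log2 ratio -1.73, adjusted exact p = 0.101) and the TATA box (1.07, 0.158) were not called either, although both log2 ratios were larger in size than in the conservative list. Over all alternatives the adjusted p ran from 1.39e-05 to 0.730 for the DRE, from 0.0113 to 0.917 for the TATA box and from 0.00327 to 0.610 for the Mad site. The other 11 fixed motifs did not pass, the nearest being the GAGA repeat (46 against 72, adjusted exact p = 0.0563). Flank tests were two-sided exact binomial tests of discordant peaks and matched tests Fisher's exact tests, each adjusted over 17 motifs. Against 5 motifs called in all, 2 were called without replicate 2 and 0 without replicate 3. The GAGA repeat was called without replicate 1 (log2 ratio -1.29, adjusted exact p = 0.0157, in a range from 0.000235 to 0.874). The long KLF box was not called without replicate 1 (log2 ratio 0.26, adjusted exact p = 0.825), 2 (1.02, 0.121) or 3 (0.54, 0.521), nor was the GATA site (0.55, 0.157; 0.44, 0.380; 0.37, 0.521). Over all alternatives the adjusted p ran from 8.59e-05 to 0.825 for the long KLF box and from 0.000357 to 0.521 for the GATA site.

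Among all 2080 6-mers, 690 differed between summits and flanks (268 higher, 422 lower), the top one being AAATAT (962 against 539 of 3287, adjusted exact p = 1.01e-31). Summit windows had a GC content of 37.5% and flanks 42.5%. Against GC-matched peaks 118 were called (54 higher, 64 lower), and AAATAT was not (adjusted exact p = 0.560). GCCCCC, AGGGGG and AGCCCC were called there at adjusted p of 3.58e-13, 3.34e-09 and 1.47e-07, and were called against flanks with each replicate left out. The count against flanks was 577, 433 and 311 without replicate 1, 2 and 3. GCCCCC was concentrated at the summit itself: away from promoters it was in 4.63% and 5.99% of the 50 bp bins on either side of the summit, and in 1.52% to 2.94% of the bins farther out.

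**Figure D5:**
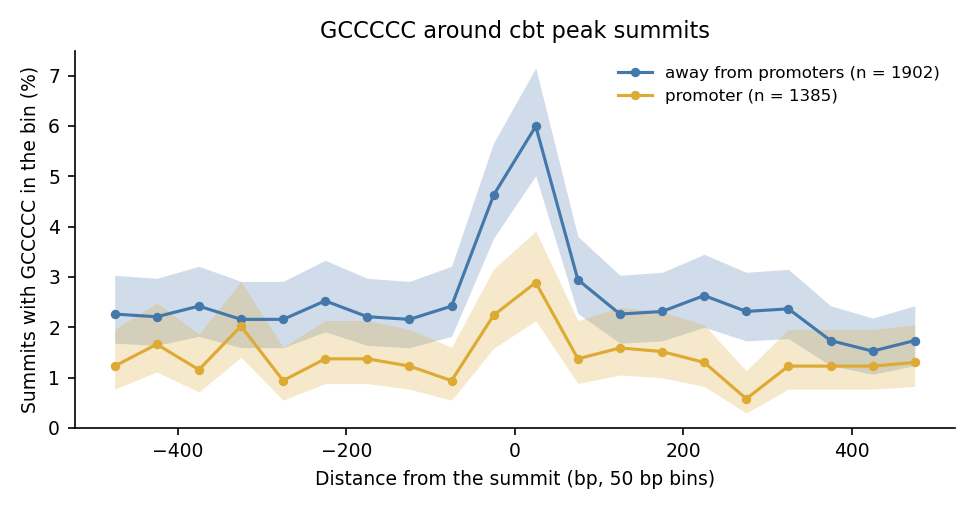
Share of summits with GCCCCC on either strand (y axis, %) in 50 bp bins by distance from the summit (x axis, bp), for 1902 summits away from promoters and 1385 at promoters; shading is the 95% Wilson interval. Both lines peak in the 2 bins next to the summit, at 5.99% away from promoters and 2.89% at promoters.

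Whether peaks with a motif were higher was also tested. The median signal of the 239 peaks with the KLF and Sp box was 125.9, against 141.2 for the 3048 without, a difference of -15.4 (two-sided permutation p = 0.0165). The direction turned in the list of 2944 peaks (1.10, permutation p = 0.909), without replicate 2 (7.65, permutation p = 0.201) and without replicate 3 (0.774, permutation p = 0.927). Without replicate 1 the difference was -6.84 (permutation p = 0.159). With a replicate left out, the signal was that of a single remaining replicate, which is on a smaller scale. The median signal was 66.67 and 61.59 in the thresholded lists of replicates 1 and 2, against 140.1 in the conservative list. The size of these differences is therefore not comparable with -15.4.

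The X chromosome, tested for whether peaks follow gene number, held 576 summits (17.5%, 16.3 to 18.9%) against 16.9% of coding starts (two-sided exact binomial p = 0.328) and 17.6% of the length of the arms (p = 0.945). A difference from either share was not detectable with this number of summits.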

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

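The left-out peaks were noticed in the data, and both tests of explanations below were chosen after that but before their own results were seen. Peaks that passed the authors' limit in the ranked lists were missing from the thresholded lists, and no control samples were analysed here to set them against. The conservative list left out 107 such peaks, of which 102 were on the arms, 61 of them on 3R and 25 on 2L. They fell in 40 regions, and 11 regions of 3 or more held 60 of them. The largest were at Hacd1 and Rh5 (2L 12003460 to 12012400, 10 peaks), at cbt (2L 471340 to 481991, 9 peaks), at Kdm2 (3R 9048298 to 9057577, 9 peaks) and at tara (3R 16224514 to 16254250, 8 peaks). Other high left-out peaks were near corto (signal 2111), CG18622 (1686) and Lk6 (1394). The left-out peaks included the only summits near a start for 35 genes, among them RpL13A, Gadd45, Pgk, Sirt6, larp, Sin3A and cbt. Members of the gene lists among them, such as Sin3A for co-repressors and cbt for KLF and Sp genes, were counted as not bound above.

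For the 9 left-out peaks within 10 kb of cbt, the tagged gene, a candidate explanation is a fixed set of excluded regions: only 5 of 764 left-out peaks of the 7 lists (0.654%) overlapped a kept peak of another list, while 697 (91.2%) were left out of another list too. A strictly fixed set would give 0 and the bound set beforehand was 5%. Over the 7 lists it therefore stays open, because peaks at the edge of a region could be kept in one list and left out of another. At cbt itself, the conservative list and the 3 replicates left out every passing summit from 2L 471309 to 482007. Within 10 kb of cbt they kept every passing summit at or below 470841 or at or above 483529. That is the pattern of a single fixed interval at cbt, and what set it was not tested. Extra copies of the region in the tagged strain are a further candidate explanation: 12 of 93 ranked replicate peaks near cbt (2 of 35, 6 of 28 and 4 of 30) were under the median signal of their list, and peaks spanned 76.1-fold to 219-fold within a replicate. The bound written beforehand took any peak under the median as evidence against extra copies, which was wrong, because a weak peak whose signal is doubled can still be under the median, so these peaks and a raised copy number cannot be told apart. No biological explanation was tested, since the design has 1 group.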

How the results depend on the processing

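The alternatives at other IDR limits, with added-back peaks, with equal peak numbers, with peaks in all 3 replicates, with another matched draw, with ranked peaks as the promoter background, and with a replicate left out of overlap and correlation were chosen after seeing the data, and the rest before. The 28 alternatives gave 799 values. Of those that answer a comparison, 93 kept their direction and side of the threshold or their size, 25 moved in size, 8 fell short of the threshold, 1 passed it and 3 turned; of single lists, motifs, 6-mers and pairs, 623 kept it, 30 fell short, 13 passed and 3 turned. Promoter share (30.1% to 53.6%), replicate overlap as a mean over ordered pairs (58.2% to 73.1%) and the X share kept their side of the threshold in every alternative run. The 4 called gene lists and GCCCCC, AGGGGG and AGCCCC did so too. Single pairs of replicates ran from 44.0% (replicate 1 in 2) to 92.3% (replicate 2 in 3). A limit of 0.01 changed nothing, because every thresholded list already stops there. Its values are among those counted as kept above, although that was fixed in advance.

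The KLF box difference in signal (-15.4) was -8.71 in the list of 2736 peaks and 1.10 in that of 2944. It was -10.8 at IDR under 0.001, -9.77 with the long box and -21.7 at promoters. With a replicate left out it was -6.84 to 7.65 in a single replicate's own signal, which is on another scale. It turned without replicate 2 (7.65) and replicate 3 (0.774). Called fixed motifs (5) were 3 in the list of 4724 peaks and at IDR under 0.05, 2 at 25 bp, against GC-matched peaks and in another draw, and 0 to 4 with a replicate left out. Called 6-mers (690) were 340 at 25 bp, 118 and 133 in the matched draws, and 311 to 577 with a replicate left out. Bound genes (1686) were 1049 at IDR under 0.001 and 765 to 959 with a replicate left out, where fewer peaks remain by construction. Called gene lists (4) were 7 by nearest start within 5 kb. Mean signal correlation (0.776) was 0.344 over all ranked peaks. With a replicate left out a single pair remains, so the range of 0.746 to 0.806 only restates the values of the pairs. The promoter difference of regions in all 3 replicates (5.36 points) was 0.755 at 200 bp and 2.79 to 7.99 with a replicate left out, and the box difference (-1.39 points) was -2.02 to -0.782. At IDR under 0.001, which keeps fewer peaks by construction, the conservative list held 1764 peaks, the lists of 2736, 2944 and 4724 peaks 1430, 1759 and 2328, and replicates 1 and 2 1346 and 1008. The KLF and Sp box turned without replicate 1 (log2 ratio -0.65 to -0.18 with a replicate left out), the TATA box in another draw (-0.063) and TGF-beta genes by nearest start (23.5 points). Apart from the fewer peaks named above, the cause was not tested. No paired analysis was possible because there is 1 group. Depth is unknown, so what it limits cannot be stated.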

Other observations

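The gene families and the chromosome 4 count in this part were chosen after the data were seen, and the tests of explanations were chosen after each pattern but before their own results. Genes for cuticle proteins and ionotropic receptors had no promoter peaks. None of 120 cuticle protein genes was bound (up to 2.50%, adjusted exact p = 3.94e-06), none of 60 ionotropic receptor genes (up to 5.0%, 0.00634), 2 of 83 cytochrome P450 genes (2.41%, 0.0149; Cyp6u1 and Cyp317a1) and 1 of 51 odorant-binding protein genes (1.96%, 0.0570). The cyclophilin genes Cyp1 and Cyp40, first counted as cytochrome P450 by their symbols, were taken out after the values were seen, and this lowered that adjusted p. Translation initiation and elongation factors had 12 of 52 bound (23.1%, 0.0757), led by eIF6 and eEF1gamma. Of the other families, 5 of 33 vacuolar ATPase genes, 4 of 35 glutathione S-transferases, 3 of 17 aminoacyl-tRNA synthetases, 2 of 28 Rab GTPases, 1 of 35 UDP-glycosyltransferases, 1 of 8 chaperonin genes and 1 of 8 sugar transporters were bound, and none passed over the 13 families.

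Chromosome 4 held 6 summits (0.182%, 0.0837 to 0.398%), against 1.01% of the length of the arms (two-sided exact binomial p = 1.42e-08) and 0.724% of coding starts (exact p = 3.06e-05), and 4 of its 80 coding genes were bound. In the conservative list 98 peaks (2.98%) had a signal under 20, although the replicate peaks that overlapped them had a median of 0.742 times that of the matched peaks. Those replicate values can belong to a neighbouring summit.

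The peaks at cytoplasmic ribosomal protein genes are a pattern that strong transcription could produce in any precipitate. Genes of the respiratory chain and ATP synthase were taken as strongly transcribed from background knowledge, since no expression values were used here. Of these, 7 of 65 (10.8%) were bound, against 11.8% of other genes (exact p = 1.00) and 57.0% of ribosomal genes (exact p = 2.85e-09). That family did not share the pattern, but a single family of unmeasured expression cannot decide the question. Translation initiation and elongation factors, with 12 of 52 bound (23.1%), lay above other genes without being called (adjusted exact p = 0.0757). Base composition around the start is argued against, since 0% of 10000 sets of other genes matched on GC content held 49 bound genes, with a mean of 10.4 and a highest of 23. Whether any precipitate would pull down these promoters stays open, because no control precipitate was analysed here. The same question stays open for the sugar and stress lists, and for the families with few or no promoter peaks. No biological explanation was tested, since the design has 1 group.

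Base composition was a candidate explanation of the C-run 6-mers at summits. They were higher at summits than in flanks although summit windows were poorer in GC (37.5% against 42.5%). Lower GC content by itself would give fewer C-runs at summits, so this difference in GC argues against composition as the source of the excess over flanks. In the GC-matched comparison, 3 of 3 C-run 6-mers were higher at summits, the weakest at an adjusted exact p of 1.47e-07. That comparison is the one already given in the Results and not a separate test. It shows that the excess remains when GC content is matched. A general property of promoters is argued against by the 1902 summits away from promoters, of which 9.57% held GCCCCC against 3.94% of their flanks (182 against 75, exact p = 8.86e-12). At promoters it was in 68 summits against 42 flanks of 1385 (exact p = 0.0167). The hypothesis that cabut, or a partner, may recognise C-runs was not tested further, and no biological explanation was tested, since the design has 1 group.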
